A study of Mus musculus with 177 samples.

How the data were processed

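Newborn C57BL/6 mice at postnatal day 7, 62 in the design text, breathed a low-oxygen gas (an inspired oxygen fraction of 0.08) or air for 120 min. A reoxygenation phase of 30 min with 21, 40, 60 or 100% oxygen followed, and then 150 min in air before lung, brain and eye were collected. The hypoxia groups are named H21, H40, H60 and H100 here, and the groups without hypoxia N21 and N100, after the oxygen percentage of the 30 min phase. The series holds 177 Affymetrix Mouse Gene 1.0 ST arrays, 61 of lung, 59 of brain and 57 of eye. Group and replicate number were taken from the sample titles.

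Per the labels' protocols, 10 ng of total RNA per array was made into biotin-labelled product. The protocol text describes a Ficoll gradient and a blood RNA kit, while the design text names solid tissue stored in RNAlater. The authors deposited log2 values after RMA, a method that corrects background, equalizes the distributions of arrays and summarizes probes into probe sets. Its version is not stated. In the deposited log2 table the sorted values of every array lay within 0.0961 of its tissue's mean distribution, and the median differed between tissues (6.25 in lung, 6.07 in brain, 6.35 in eye). The tissues were therefore treated as normalized separately, and levels were not compared between tissues except as differences of changes. Values ran from 1.50 to 14.5 on the log2 scale. The number of arrays limits the precision, and no depth applies to array values.

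Of 34760 probe sets, the platform annotation gives 21640 exactly 1 gene symbol, 1321 several and 11799 none. The Entrez identifier of 21553 of the first kind was found in the RefSeq gene table, which supplied current symbols. For genes with several probe sets, the one with the highest mean in the tissue was used, which left 19937 genes.

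Changes were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided) and data.table (version 1.17.8), with all 6 groups of a tissue in 1 fit. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and errors given as ± are standard errors of the fit. In each tissue the comparisons were each hypoxia group and N100 against N21, H100 against H21, H100 against N100, the slope over reoxygenation oxygen within the 4 hypoxia groups as the change from 21 to 100%, and the interaction of hypoxia with 100% oxygen. The H21 minus N21 change was also compared between tissues in 1 fit of all arrays. For 47 gene lists, of which 720 of 779 entries matched a tested gene, camera compared each list with the other genes at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Member counts are given adjusted over all genes and adjusted within the list.

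These comparisons, the lists, the alternatives fixed at the outset and the rule for named genes were fixed before the data were examined. The rule names up to 12 called genes per direction for H21 and H100 against N21, up to 5 for other comparisons, and the 3 smallest adjusted p where no gene was called. It skips predicted genes, chemosensory receptors and small RNAs. For a described list it names 2 to 4 called members by size of change, or the 2 largest as values. Chosen after the data were examined were the comparison of all hypoxia with all normoxia groups and its tissue differences, its 12 genes per direction, the lists described, 3 arrays with the profile of another tissue and their removal, and the removal of each array in turn. In the comparison of all hypoxia with all normoxia those 3 arrays were left out.

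Alternatives fixed at the outset were array quality weights, leaving out the dimmest 40% of genes, quantile normalization again, the replicate number as a block, the submission run as a block, only the groups named in the fit, every probe set tested, a sex covariate, and the inter-gene correlation estimated from the data. Arrays with a median correlation more than 3 median absolute deviations below the tissue's median (2 of lung, 6 of brain, 6 of eye) were left out as an added alternative, as were all arrays after the first submission run. Submission runs are not stated by the labels. They were read from the order of the sample records as a possible processing batch: a first run ordered by group, a second with about 1 array of each group, and the remainder. Sex was read from the arrays as log2 Xist minus the mean of the Y-linked genes.

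The fits were tested on simulated data in which 200 of 19937 genes were changed, 100 by 0.5 and 100 by 1 on the log2 scale. For H21 minus N21 the test called 60 of 100 of the smaller changes in lung, 62 in brain and 72 in eye, and 96, 100 and 99 of the larger. For the difference of H21 minus N21 between lung and brain it called 19 of the smaller and 87 of the larger.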

Results

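Gene expression was measured in lung, brain and eye of newborn mice about 3 hours after low oxygen. Air or more oxygen had followed for 30 min. Lung had 9 N21, 10 N100, 9 H21, 10 H40, 12 H60 and 11 H100 arrays. Brain had 9, 9, 9, 10, 11 and 11 in the same order, and eye 9, 9, 9, 10, 9 and 11. The design text describes randomized mice, so arrays of a group and tissue were taken as separate animals.

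Tissue markers placed 174 of the 177 arrays with their label. The array labelled Lung H40 replicate 10 correlated best with brain (r = 0.986 against 0.816 with lung, across genes), and the mean of its type 2 alveolar cell genes, which make surfactant, was 6.37 on the log2 scale against 11.29 ± 0.16 (SD, n = 9) in the other H40 lungs. The array labelled Brain H40 replicate 7 correlated best with eye (r = 0.959 against 0.874 with brain), and its neuron genes averaged 8.52 against 10.68 ± 0.13 (SD, n = 9). The array labelled Eye H40 replicate 9 correlated best with lung (r = 0.956 against 0.880 with eye), and its lens crystallins averaged 6.03 against 12.78 ± 0.19 (SD, n = 9). Genes are not independent replicates in these correlations. Comparisons fixed beforehand include these 3 arrays, and the counts without them stand beside each count they move.

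**Figure D1:**
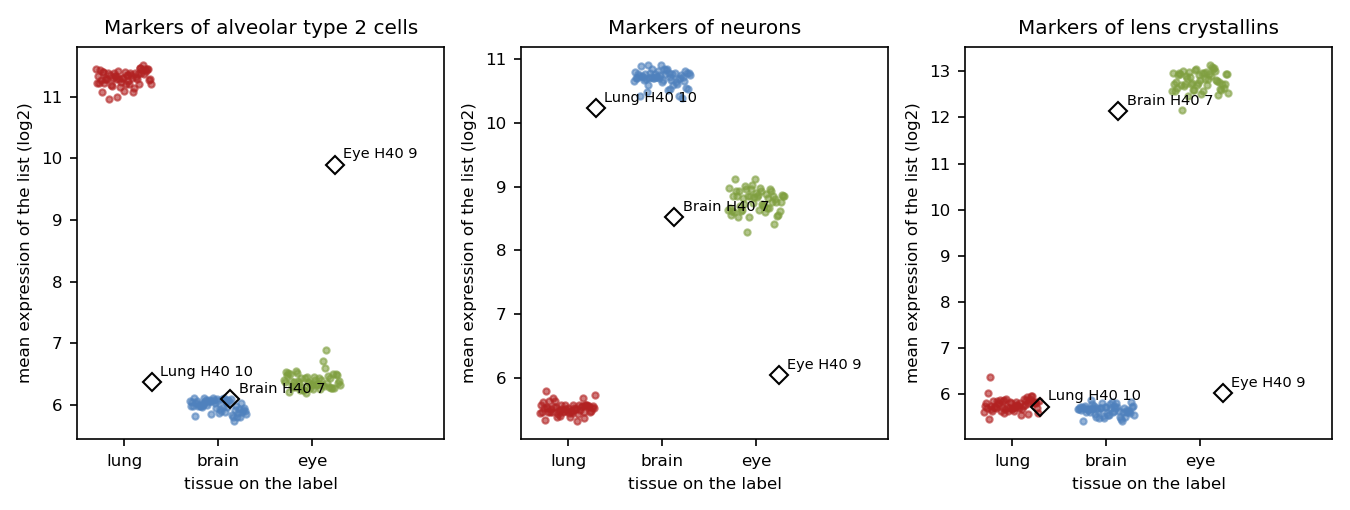
Mean log2 expression of the type 2 alveolar cell, neuron and lens crystallin lists (vertical axes) in each array of lung, brain and eye (horizontal axis); each point is 1 array, and the arrays labelled Lung H40 replicate 10, Brain H40 replicate 7 and Eye H40 replicate 9 are marked. In this order the marked arrays lie at 6.37, 8.52 and 6.03, away from the others of their label.

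Between the first submission run and the later ones, limma called 11256 of 19937 genes in lung (38 against 22 arrays), 8933 in brain (38 against 20) and 7714 in eye (37 against 19). The groups were spread unevenly over the runs: 8 of the 9 or 10 N100 arrays of each tissue belonged to the first run, against 5 of 9 N21 arrays. Counts with the run as a block (blocked by run) and in the first run are given below. The second run held 1 or 2 arrays of each group, and the third 0 to 4, too few for values of their own.

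Of the 47 lists camera called 12, 23, 11 and 8 for lung H21, H40, H60 and H100 against N21, 2 for N100 against N21, 3 for H100 minus H21, 8 for H100 minus N100, 13 for the slope over oxygen, 3 for the interaction and 12 for all hypoxia minus all normoxia. In the same order brain had 6, 17, 5, 11, 2, 4, 2, 13, 1 and 7, and eye 4, 21, 6, 6, 7, 0, 4, 2, 5 and 12. Without the array of another tissue the H40 counts were 14 in lung, 2 in brain and 12 in eye. With estimated correlation 1 list was called for lung H100 and for brain H40 against N21, 2 for brain H21 against N21, 4, 2 and 1 for all hypoxia in lung, brain and eye, and 0 elsewhere. The lists described were chosen after the data were examined and are a part of those called. Each is given with its p with estimated correlation, which is adjusted too, and a range over the other alternatives unless all stayed under 0.05. Counts adjusted within a list and not given were 0.

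In lung, the comparison of all 41 hypoxia with all 19 normoxia arrays, chosen after the data were examined, called 331 genes, 210 higher and 121 lower after hypoxia. Fhl5, a LIM domain protein of smooth muscle and testis, rose by 1.37 ± 0.18 (adjusted p = 1.3e-06), and its values lay above the normoxia mean in 37 of 41 hypoxia arrays. Dpep1, a dipeptidase that cleaves leukotriene D4, rose by 1.12 ± 0.14 (adjusted p = 1.1e-07, 39 of 41 arrays), and the neutrophil collagenase Mmp8 by 0.91 ± 0.15 (adjusted p = 0.00013, 40 of 41). Ntrk2, the receptor of brain-derived neurotrophic factor, rose by 0.73 ± 0.08 (adjusted p = 4.3e-08, 41 of 41). Adm, which encodes the vasodilator adrenomedullin, rose by 0.71 ± 0.10 (adjusted p = 1.3e-06, 39 of 41), and Xdh, the enzyme that makes uric acid, by 0.72 ± 0.11 (adjusted p = 2.5e-05, 39 of 41). Fmo2 (0.85 ± 0.13), Ms4a4a (0.77 ± 0.21), Inmt (0.74 ± 0.16), Gdpd2 (0.73 ± 0.11), Adamtsl2 (0.73 ± 0.12) and Tinagl1 (0.69 ± 0.10) completed the 12 largest increases, with adjusted p between 1.2e-05 and 0.037 and at least 36 of 41 arrays above the normoxia mean.

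Among lung genes that were lower after hypoxia, Slitrk6 fell by 0.83 ± 0.15 (adjusted p = 0.00022) and the netrin receptor Unc5c by 0.58 ± 0.11 (adjusted p = 0.00043). They lay below the normoxia mean in 38 and 37 of 41 arrays. Among the 12 largest decreases Wnt2, a signal of lung mesenchyme, changed by -0.51 ± 0.12 (adjusted p = 0.011, 37 of 41 arrays) and Bmp5 by -0.46 ± 0.11 (adjusted p = 0.012, 37 of 41). The metalloprotease Adam12 changed by -0.51 ± 0.08 (adjusted p = 9.2e-05, 38 of 41) and the endothelial adhesion molecule Vcam1 by -0.50 ± 0.13 (adjusted p = 0.026, 35 of 41). The others were Slc27a6 (-0.55 ± 0.10), Iigp1 (-0.51 ± 0.13), Stc1 (-0.48 ± 0.08), Tafa1 (-0.46 ± 0.09), Glrb (-0.46 ± 0.10) and Ptprd (-0.45 ± 0.10), with adjusted p between 9.2e-05 and 0.026.

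By list, 6 of 22 glucocorticoid-responsive genes rose in lung after hypoxia, 0 fell and 16 did not pass, and 15 rose adjusted within the list. Sult1a1 rose by 0.66 ± 0.09, Sgk1 by 0.48 ± 0.08, Tsc22d3 by 0.42 ± 0.11 and Map3k6 by 0.38 ± 0.09. The list had a mean change of 0.27 (camera adjusted p = 5.3e-16, p = 0.014 with estimated correlation). Of 31 targets of hypoxia-inducible factor (HIF), 5 rose, among them Adm, Hif3a (0.58 ± 0.14), Bnip3 (0.36 ± 0.09) and P4ha2 (0.33 ± 0.07), and 26 did not pass, with 7 higher and 1 lower adjusted within the list (list adjusted p = 0.0011, p = 0.014 with estimated correlation). Of 28 DNA replication genes 3 fell, Mcm6 (-0.28 ± 0.06), Mcm5 (-0.23 ± 0.06) and Mcm7 (-0.21 ± 0.05), which encode parts of the replicative helicase. Another 25 did not pass, and 13 fell adjusted within the list (list adjusted p = 8.4e-18, p = 0.049 with estimated correlation).

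Of 12 neutrophil genes only Mmp8 passed over all genes, and 8 rose adjusted within the list (list adjusted p = 5.1e-08, p = 0.059 with estimated correlation). Of 10 genes of smooth muscle and pericytes, Tagln (0.22 ± 0.06) and Cspg4 (0.18 ± 0.05) rose and 8 did not pass, with 4 higher adjusted within the list (list adjusted p = 0.00013, p = 0.014 with estimated correlation, range 2.2e-05 to 0.18). Of 14 glycolysis genes Pfkl rose (0.30 ± 0.06) and 13 did not pass, with 6 higher adjusted within the list (list adjusted p = 0.00028, p = 0.25 with estimated correlation). Vegfa (-0.04 ± 0.06), Hmox1 (-0.07 ± 0.07), Fos (0.01 ± 0.06) and Per1 (0.42 ± 0.14) did not pass. Blocked by run 504 lung genes were called, which included the 331 in the same direction, and in the first run 23 were called. The count was 834 with array quality weights and 95 with the array labelled Lung H40 replicate 10 included, and of the 331 genes 331 kept their direction.

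**Figure D2:**
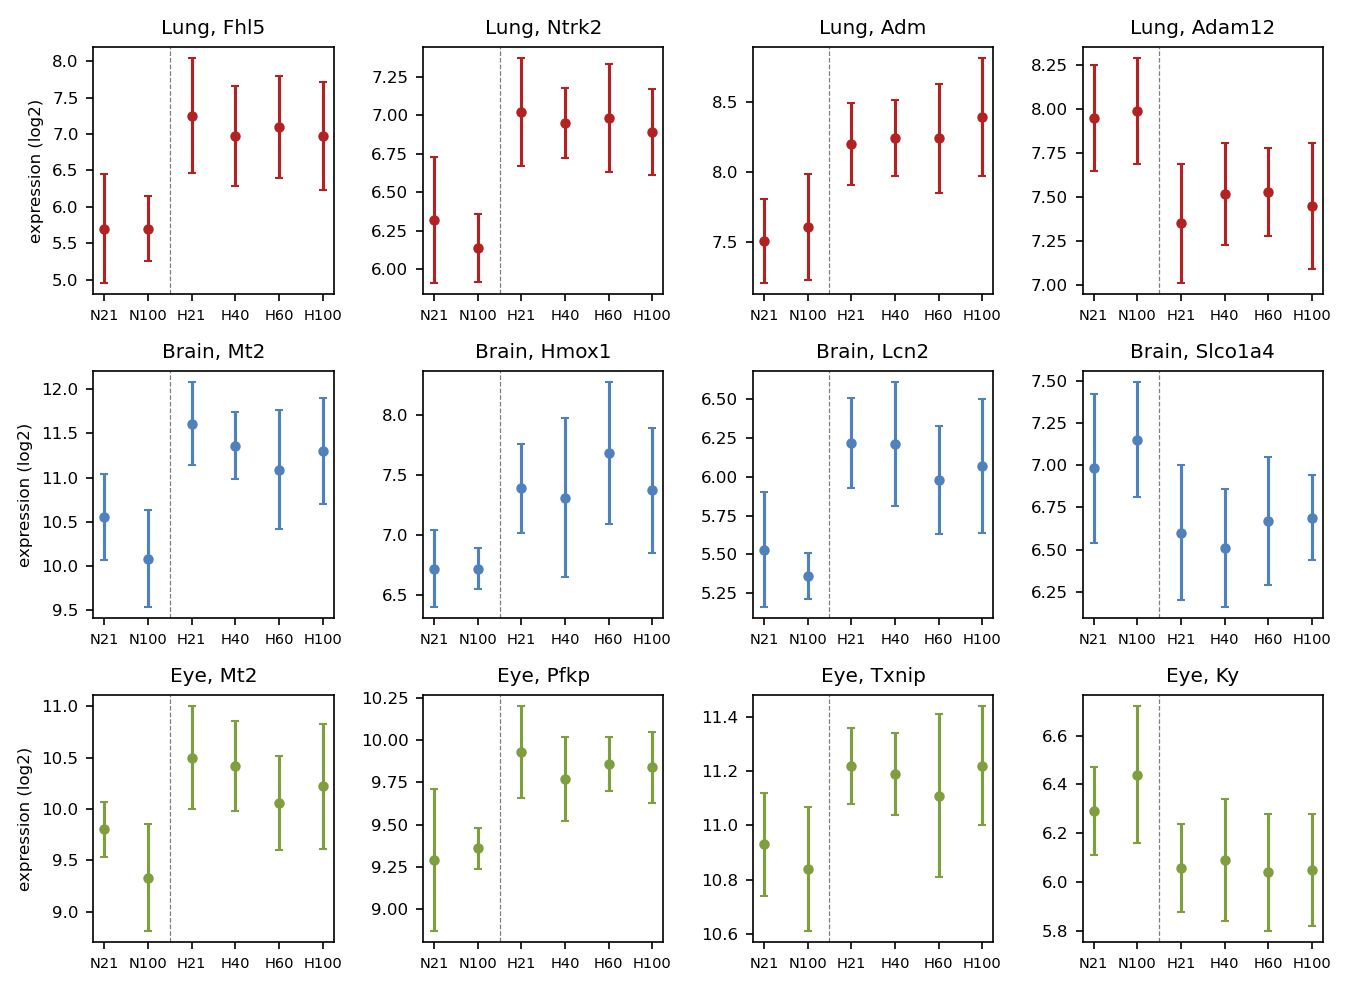
Group means of log2 expression with SD error bars (vertical axes) for the 6 exposure groups (horizontal axis) of lung (Fhl5, Ntrk2, Adm, Adam12), brain (Mt2, Hmox1, Lcn2, Slco1a4) and eye (Mt2, Pfkp, Txnip, Ky), without the 3 arrays of another tissue. Adm in lung averaged 7.51 in N21 and 7.61 in N100 against 8.20 to 8.39 in the 4 hypoxia groups, and Mt2 in brain 10.55 and 10.08 against 11.09 to 11.61.

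Hypoxia followed by air was compared with the air control in 9 H21 and 9 N21 lungs. Glul, which encodes glutamine synthetase, rose by 0.52 ± 0.11 (adjusted p = 0.047), and Sec14l2, a lipid-binding protein, by 0.35 ± 0.07 (adjusted p = 0.021). Ldb2, a cofactor of LIM proteins, fell by 0.49 ± 0.09 (adjusted p = 0.021). Over the 41 hypoxia lungs of all groups, Glul lay above the normoxia mean in 40, Sec14l2 in 37, and Ldb2 below it in 40. No other gene was called, and 726 had an unadjusted p under 0.05. DNA replication genes fell as a list (mean -0.21, adjusted p = 7.3e-19, p = 0.11 with estimated correlation), with 0 of 28 called and 2 lower adjusted within the list; Mcm6 was at -0.38 ± 0.11 and Pola1 at -0.33 ± 0.18. Glucocorticoid-responsive genes rose as a list (mean 0.29, adjusted p = 3e-09, p = 0.11 with estimated correlation), with 0 of 22 called and 2 higher adjusted within the list; Sult1a1 was at 0.77 ± 0.20 and Lcn2 at 0.51 ± 0.29. Neutrophil genes rose as a list (mean 0.37, adjusted p = 5.6e-07, p = 0.17 with estimated correlation), with 0 of 12 called and 1 higher adjusted within the list; Mmp8 was at 0.99 ± 0.27 and Cxcr2 at 0.58 ± 0.24.

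Other lists passed in the same lungs and lost that call in an alternative. HIF targets (0 of 31 called, 2 adjusted within the list, adjusted p = 0.013, p = 0.11 with estimated correlation) had a range of 0.0045 to 0.31. Adm was at 0.70 ± 0.19 and Bnip3 at 0.48 ± 0.16. Skeletal muscle genes (0 of 14 called or adjusted within the list, adjusted p = 0.021, p = 0.93 with estimated correlation) had 0.00011 to 0.48. Myh8 was at 0.86 ± 0.76 and Tnnc2 at 0.84 ± 0.58. T and B lymphocyte genes (0 of 12 called or adjusted within the list, adjusted p = 0.0098, p = 0.93 with estimated correlation) had 0.012 to 0.7. Rag1 was at 0.48 ± 0.50 and Cd3g at 0.47 ± 0.31. The count of 3 genes was 133 with weights, 27 without low-correlation arrays, 5 blocked by run, 0 in the first run and 10 without the array of another tissue. With sex as a covariate, uneven here (8 of 9 N21 and 5 of 9 H21 lungs female), it was 0. It was 16 without N21 replicate 2, 0 without N21 replicate 1, 5, 7 or 9, and 1 without H21 replicate 1, 3 or 5 or N21 replicate 3 or 6.

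After 40% oxygen (10 H40 and 9 N21 lungs) limma called 0 genes, with 1404 at unadjusted p < 0.05. The smallest adjusted p belonged to Ldb2 (-0.46 ± 0.09, adjusted p = 0.076), Ntrk2 (0.82 ± 0.18, adjusted p = 0.19) and the glycolytic enzyme Pfkl (0.45 ± 0.10, adjusted p = 0.23). Glycolysis genes rose as a list (mean 0.37, adjusted p = 3.6e-11, p = 0.068 with estimated correlation), with 0 of 14 called and 10 higher adjusted within the list, and with Aldoa at 0.57 ± 0.15 and Eno2 at 0.56 ± 0.29. DNA replication genes fell as a list (adjusted p = 2.2e-11, p = 0.37 with estimated correlation, 0 of 28 called). Mcm4 was at -0.34 ± 0.14 and Mcm3 at -0.34 ± 0.15. Glucocorticoid-responsive genes rose (adjusted p = 0.0019, p = 0.49 with estimated correlation, 0 of 22 called). Zbtb16 was at 0.77 ± 0.49 and Fkbp5 at 0.49 ± 0.22. Type 2 alveolar cell genes fell (adjusted p = 7.9e-08, p = 0.37 with estimated correlation, 0 of 12 called) and neuron genes rose (adjusted p = 5.1e-06, p = 0.49 with estimated correlation, 0 of 14 called). Lamp3 was at -0.84 ± 0.39 and Sftpc at -0.81 ± 0.47 among the alveolar genes. Syt1 was at 0.73 ± 0.38 and Nefl at 0.60 ± 0.32 among the neuron genes. Without the array labelled Lung H40 replicate 10 the adjusted p of these lists became 0.23 and 0.87 (ranges 6.7e-07 to 0.23 and 2.5e-05 to 0.89), and Sftpc was at 0.02. The count was 4 with weights, 1 blocked by run, 0 in the first run, 4 without N21 replicate 2, 4 without H40 replicate 2, and 1 without H40 replicate 8 or 10.

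After 60% oxygen (12 H60 and 9 N21 lungs) limma called 0 genes, with 425 at unadjusted p < 0.05. Fhl5 was at 1.40 ± 0.31 (adjusted p = 0.35), Ldb2 at -0.38 ± 0.09 (adjusted p = 0.35) and Gdpd2 at 0.74 ± 0.18 (adjusted p = 0.53). DNA replication genes (adjusted p = 1.6e-11, p = 0.43 with estimated correlation, 0 of 28 called) and genes of oxidative phosphorylation (adjusted p = 1.8e-08, p = 0.88 with estimated correlation, 0 of 42 called) fell as lists. Mcm6 was at -0.30 ± 0.10 and Uhrf1 at -0.27 ± 0.14 among the DNA replication genes. Ndufv1 was at -0.28 ± 0.13 and Atp5o at -0.26 ± 0.16 in oxidative phosphorylation. Neutrophil genes rose (adjusted p = 9.8e-06, p = 0.43 with estimated correlation, 0 of 12 called and 1 higher adjusted within the list). Mmp8 was at 0.79 ± 0.25 and Cxcr2 at 0.57 ± 0.23. Glucocorticoid-responsive genes rose (adjusted p = 9.8e-06, p = 0.43 with estimated correlation, 0 of 22 called and 2 higher adjusted within the list), range 2.2e-06 to 0.13. Sult1a1 was at 0.55 ± 0.18 and Sgk1 at 0.54 ± 0.17. Brown fat genes fell (adjusted p = 0.0012, p = 0.68 with estimated correlation, 0 of 7 called), range 0.0031 to 0.26. Ucp1 was at -1.13 ± 0.87 and Cox8b at -0.54 ± 0.55. The count stayed at 0 blocked by run and in the first run, and was 4 with weights and 2 without N21 replicate 2.

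After 100% oxygen (11 H100 and 9 N21 lungs) limma called 0 genes, with 419 at unadjusted p < 0.05. Ldb2 was at -0.43 ± 0.09 (adjusted p = 0.096), Adm at 0.89 ± 0.18 (adjusted p = 0.096) and Gdpd2 at 0.80 ± 0.18 (adjusted p = 0.25). DNA replication genes fell as a list (mean -0.19, adjusted p = 6.7e-25, p = 0.046 with estimated correlation), with 0 of 28 called and 2 lower adjusted within the list, Mcm6 being at -0.33 ± 0.11 and Uhrf1 at -0.32 ± 0.14. Glucocorticoid-responsive genes (adjusted p = 1.9e-09, p = 0.1 with estimated correlation, 0 of 22 called) and neutrophil genes (adjusted p = 1.6e-07, p = 0.13 with estimated correlation, 0 of 12 called and 3 higher adjusted within the list) rose. Zbtb16 was at 0.73 ± 0.47 and Sult1a1 at 0.57 ± 0.19 among the glucocorticoid genes. Mmp8 was at 0.93 ± 0.26 and Cxcr2 at 0.64 ± 0.23 among the neutrophil genes. HIF targets rose (adjusted p = 0.021, p = 0.1 with estimated correlation, 0 of 31 called and 1 higher adjusted within the list), range 0.019 to 0.18. Hif3a was at 0.53 ± 0.22. The count was 0 blocked by run and in the first run, 8 with weights, 4 without the array of another tissue, 5 without N21 replicate 2 and 6 without H100 replicate 6.

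Hypoxia was also compared with its absence where both groups breathed 100% oxygen (11 H100 and 10 N100 lungs), and 5 genes were called. Vegfc, a growth factor of lymphatic vessels, rose by 0.74 ± 0.13 (adjusted p = 0.0072), and Glul (0.49 ± 0.10) and the endothelial junction molecule Jam2 (0.49 ± 0.10) rose with an adjusted p of 0.038 each. Stc1, which encodes the hormone stanniocalcin, changed by -0.62 ± 0.13 and Ldb2 by -0.41 ± 0.09 (adjusted p = 0.038 each). Over all 41 hypoxia lungs Vegfc lay above the normoxia mean in 39, Jam2 in 37, and Stc1 below it in 38. Glucocorticoid-responsive genes rose as a list (adjusted p = 7.9e-09, p = 0.31 with estimated correlation, 0 of 22 called and 5 higher adjusted within the list), Zbtb16 being at 1.05 ± 0.46 and Gpd1 at -0.67 ± 0.36. Neutrophil genes rose (adjusted p = 6.7e-05, p = 0.47 with estimated correlation, 0 of 12 called and 1 higher adjusted within the list) and DNA replication genes fell (adjusted p = 2.6e-11, p = 0.35 with estimated correlation, 0 of 28 called). Mmp8 was at 1.02 ± 0.25 and S100a8 at 0.69 ± 0.26 among the neutrophil genes. Mcm3 was at -0.35 ± 0.14 and Mcm4 at -0.32 ± 0.13 among the DNA replication genes. Brown fat genes fell (adjusted p = 0.0024, p = 0.74 with estimated correlation, 0 of 7 called), range 0.0042 to 0.1. Ucp1 was at -1.50 ± 0.86 and Cidea at -1.03 ± 0.64. The count of 5 was 183 with weights, 28 without low-correlation arrays, 4 blocked by run, 0 in the first run and 21 without the array of another tissue. Leaving out any of 19 of the 21 arrays moved it over 1.5 times, to 25 without H100 replicate 6 and to 1 or 2 without the others.

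Oxygen at 100% without hypoxia (10 N100 against 9 N21 lungs) gave 0 genes, with 226 at unadjusted p < 0.05. Cyp3a16 was at 0.44 ± 0.12, Ifnk at 0.23 ± 0.07 and Zfp709 at 0.45 ± 0.15 (adjusted p = 1 each). Heat shock protein genes rose as a list (adjusted p = 0.035, p = 0.98 with estimated correlation, 0 of 14 called), range 0.0086 to 0.16. Hsph1 was at 0.54 ± 0.40 and Hspa1a at 0.42 ± 0.38. Oxidative phosphorylation genes fell (adjusted p = 0.035, p = 0.98 with estimated correlation, 0 of 42 called), range 0.0043 to 0.45. Ndufa1 was at -0.34 ± 0.29 and Cox8a at -0.25 ± 0.23. The count was 1 blocked by run and 0 in the first run.

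After the same hypoxia, limma called 0 genes between 11 H100 and 9 H21 lungs, with 211 at unadjusted p < 0.05. Cdk5rap1 was at 0.32 ± 0.10, Figla at -0.30 ± 0.09 and Sh2d4b at -0.19 ± 0.06 (adjusted p = 1 each). Skeletal muscle genes fell as a list (mean -0.60, adjusted p = 8.2e-09, p = 0.73 with estimated correlation, 0 of 14 called), range 8.7e-08 to 0.085. Myh8 was at -1.34 ± 0.73 and Tnnc2 at -1.07 ± 0.55. T and B lymphocyte genes fell (mean -0.33, adjusted p = 4.9e-08, p = 0.44 with estimated correlation, 0 of 12 called). Rag1 was at -0.99 ± 0.48 and Cd8a at -0.63 ± 0.33. The slope from 21 to 100% oxygen over the 42 hypoxia lungs likewise gave 0 genes (202 at unadjusted p < 0.05), with Figla at -0.30 ± 0.09, Sprr2e at -0.37 ± 0.11 and Trim68 at 0.23 ± 0.07 (adjusted p = 1 each). Skeletal muscle genes fell along it (adjusted p = 1.3e-11, p = 0.53 with estimated correlation, 0 of 14 called), as did T and B lymphocyte genes (adjusted p = 0.00031, p = 0.77 with estimated correlation, 0 of 12 called). Myh8 was at -1.39 ± 0.66 and Acta1 at -1.15 ± 0.58 among the skeletal muscle genes. Rag1 was at -1.04 ± 0.49 and Cd8a at -0.60 ± 0.36 among the lymphocyte genes. The interaction of hypoxia and 100% oxygen gave 0 genes (348 at unadjusted p < 0.05), with Mab21l3 at -0.42 ± 0.13, Tmem114 at -0.41 ± 0.13 and Tex19.1 at -0.38 ± 0.12 (adjusted p = 1 each). The same lists fell in it, skeletal muscle with Myh8 at -1.78 ± 1.04 and Acta1 at -1.48 ± 0.94 (adjusted p = 4e-05, p = 1 with estimated correlation, range 0.00013 to 0.072) and lymphocytes with Cd8a at -0.69 ± 0.47 and Rag1 at -0.60 ± 0.68 (adjusted p = 4e-05, p = 1 with estimated correlation, range 8.2e-05 to 0.1), with 0 members of either called. Blocked by run each of the 3 counts was 0, and in the first run 0, 1 and 0.

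In brain, all 40 hypoxia arrays were compared with all 18 normoxia arrays, a comparison chosen after the data were examined, and 17 genes were called, 16 higher and 1 lower. The metallothioneins Mt2 and Mt1, which bind zinc, rose by 1.03 ± 0.15 (adjusted p = 2.2e-05) and 0.56 ± 0.09 (adjusted p = 0.00049), each above the normoxia mean in 38 of 40 arrays. The chemokine Ccl12 rose by 0.77 ± 0.12 (adjusted p = 8.8e-05, 38 of 40), and Hmox1, the heme oxygenase that makes carbon monoxide and biliverdin, by 0.72 ± 0.13 (adjusted p = 0.0017, 35 of 40). The acute-phase genes Lcn2 (0.67 ± 0.09, adjusted p = 2.2e-05, 37 of 40), Serpina3n (0.56 ± 0.09, adjusted p = 0.00057, 38 of 40) and A2m (0.46 ± 0.07, adjusted p = 3e-05, 39 of 40) rose, as did the oncostatin M receptor Osmr (0.46 ± 0.09, adjusted p = 0.015, 38 of 40). Ctla2a (0.65 ± 0.14), Adgrl4 (0.55 ± 0.10), C5ar1 (0.37 ± 0.08) and Cnn2 (0.30 ± 0.07) also rose, with adjusted p between 0.0048 and 0.037. Slco1a4, a transporter of organic anions at the blood-brain barrier, was the gene that fell, by 0.45 ± 0.10 (adjusted p = 0.033, below the normoxia mean in 36 of 40).

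Of 22 glucocorticoid-responsive genes 4 rose in brain after hypoxia, Mt2, Lcn2, Mt1 and Fkbp5 (0.29 ± 0.06), and 18 did not pass, with 6 higher adjusted within the list (list adjusted p = 1.1e-15, p = 0.00092 with estimated correlation). HIF targets rose as a list with 0 of 31 called and 2 higher adjusted within the list (mean 0.06, adjusted p = 4.2e-07, p = 2.7e-05 with estimated correlation), the largest changes being Slc16a3 at 0.26 ± 0.06 and Pdk1 at 0.18 ± 0.04. Of 24 inflammatory genes Lcn2 rose, and 2 adjusted within the list (list adjusted p = 0.0012, p = 0.24 with estimated correlation). Interferon-stimulated genes (0 of 18, adjusted p = 0.011, p = 0.6 with estimated correlation) and glycolysis genes (0 of 14, 1 adjusted within the list, adjusted p = 0.011, p = 0.6 with estimated correlation) rose as lists, glycolysis with a range of 7.4e-05 to 0.11. Ifit1 was at 0.20 ± 0.10 and Irf9 at 0.16 ± 0.05 among the interferon-stimulated genes. Hk2 was at 0.24 ± 0.07 and Pfkl at 0.21 ± 0.09 among the glycolysis genes. Oligodendrocyte genes fell (0 of 11, adjusted p = 0.017, p = 0.6 with estimated correlation). Mobp was at -0.25 ± 0.20 and Mog at -0.22 ± 0.20. Vegfa (0.13 ± 0.05), Fos (0.11 ± 0.07) and Per1 (0.07 ± 0.06) did not pass. The count of 17 was 41 with weights, 24 blocked by run, and 4 in the first run. It was 32 without N21 replicate 2, 28 without H100 replicate 6 or H40 replicate 2, 26 without H60 replicate 1 or H21 replicate 7, and 11 without N100 replicate 3 or N21 replicate 6.

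The single brain comparisons called 0 genes. In 9 H21 against 9 N21 brains, with 175 genes at unadjusted p < 0.05, Serpina3n was at 0.76 ± 0.16 (adjusted p = 0.17), Mt2 at 1.06 ± 0.26 and the endothelial receptor Adgrl4 at 0.70 ± 0.17 (adjusted p = 1 each). Glucocorticoid-responsive genes rose as a list (0 of 22 called and 4 higher adjusted within the list, adjusted p = 3.4e-11, p = 0.0094 with estimated correlation), and so did HIF targets (0 of 31, adjusted p = 0.00019, p = 0.014 with estimated correlation). Lcn2 was at 0.69 ± 0.20 among the glucocorticoid genes. Slc16a3 was at 0.36 ± 0.13 and Bnip3 at 0.22 ± 0.13 among the HIF targets. Glycolysis genes (0 of 14, adjusted p = 0.031, p = 0.65 with estimated correlation) and inflammatory genes (0 of 24, 1 adjusted within the list, adjusted p = 0.031, p = 0.53 with estimated correlation) rose, ranges 0.0013 to 0.12 and 0.022 to 0.77. Hk2 was at 0.29 ± 0.16 and Pfkl at 0.22 ± 0.14 among the glycolysis genes. Cxcl10 was at 0.43 ± 0.16 among the inflammatory genes. The count stayed at 0 blocked by run and in the first run, and was 1 without N21 replicate 2.

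In 10 H40 against 9 N21 brains (739 genes at unadjusted p < 0.05) Lcn2 was at 0.89 ± 0.19 (adjusted p = 0.48), Ccdc190 at -0.45 ± 0.12 and Ms4a4a at 0.97 ± 0.25 (adjusted p = 0.98 each). Glucocorticoid-responsive genes (0 of 22, 2 adjusted within the list, adjusted p = 1.5e-06, p = 0.11 with estimated correlation) and HIF targets (0 of 31, adjusted p = 4.3e-05, p = 0.025 with estimated correlation) rose as lists, ranges 6.7e-07 to 0.3 and 3.8e-05 to 0.67. Mt2 was at 0.63 ± 0.26 among the glucocorticoid genes. Slc16a3 was at 0.39 ± 0.13 and Ndrg1 at 0.32 ± 0.18 among the HIF targets. Lens crystallins (0 of 17, adjusted p = 1.5e-11, p = 0.29 with estimated correlation) and rod photoreceptor genes (0 of 11, adjusted p = 2.7e-08, p = 0.29 with estimated correlation) rose. Crygd was at 0.99 ± 0.56 and Crygs at 0.90 ± 0.46 among the crystallins. Prph2 was at 0.69 ± 0.36 and Pde6b at 0.66 ± 0.35 among the rod genes. Without the array labelled Brain H40 replicate 7 their adjusted p became 0.8 and 0.34 (ranges 5.5e-12 to 0.98 and 1.2e-08 to 0.85). The count was 0 blocked by run and in the first run, and 1 without H40 replicate 2.

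In 11 H60 against 9 N21 brains (427 genes at unadjusted p < 0.05) Hmox1 was at 0.96 ± 0.26, Serpina3n at 0.54 ± 0.15 and Ccl12 at 0.67 ± 0.19 (adjusted p = 1 each). Genes of oxidative phosphorylation (0 of 42, adjusted p = 6.9e-07, p = 0.72 with estimated correlation) and of the choroid plexus (0 of 9, adjusted p = 0.0077, p = 0.72 with estimated correlation) fell as lists, and glucocorticoid-responsive genes rose (0 of 22, adjusted p = 0.00072, p = 0.72 with estimated correlation, range 0.00069 to 0.23). Cox5a was at -0.33 ± 0.20 and Ndufb9 at -0.30 ± 0.21 in oxidative phosphorylation. Ttr was at -0.35 ± 0.16 and Slc4a5 at -0.26 ± 0.17 among the choroid plexus genes. Mt2 was at 0.55 ± 0.25 and Lcn2 at 0.45 ± 0.19 among the glucocorticoid genes. In 11 H100 against 9 N21 brains (492 genes at unadjusted p < 0.05) Serpina3n was at 0.63 ± 0.15, Stat3 at 0.37 ± 0.10 and Fem1al at 0.54 ± 0.14 (adjusted p = 1 each). Glycolysis genes (0 of 14, adjusted p = 3.8e-05, p = 0.27 with estimated correlation) and glucocorticoid-responsive genes (0 of 22, 5 adjusted within the list, adjusted p = 5.7e-05, p = 0.27 with estimated correlation) rose. Hk2 was at 0.32 ± 0.16 and Pfkl at 0.30 ± 0.14 among the glycolysis genes. Mt2 was at 0.75 ± 0.25 and Lcn2 at 0.54 ± 0.19 among the glucocorticoid genes. Oxidative phosphorylation genes (0 of 42, adjusted p = 0.00032, p = 0.73 with estimated correlation) and antioxidant enzymes (0 of 16, adjusted p = 0.0019, p = 0.29 with estimated correlation) fell. Cox5a was at -0.34 ± 0.20 and Ndufa2 at -0.29 ± 0.17 in oxidative phosphorylation. Gpx1 was at -0.24 ± 0.16 and Prdx4 at -0.22 ± 0.14 among the antioxidant enzymes. Ranges were 3.6e-05 to 0.097 for glycolysis, 0.00013 to 0.84 for oxidative phosphorylation and 0.0021 to 0.097 for antioxidant enzymes. Both counts were 0 blocked by run and in the first run, and the H100 count was 1 without N21 replicate 2.

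In 11 H100 against 9 N100 brains (669 genes at unadjusted p < 0.05) Mt2 was at 1.22 ± 0.25 (adjusted p = 0.17), Ccl12 at 0.88 ± 0.19 (adjusted p = 0.19) and Fkbp5, a glucocorticoid-induced cochaperone, at 0.39 ± 0.09 (adjusted p = 0.24). Glucocorticoid-responsive genes (0 of 22, 5 adjusted within the list, adjusted p = 9.9e-07, p = 0.14 with estimated correlation) and HIF targets (0 of 31, 1 adjusted within the list, adjusted p = 0.012, p = 0.14 with estimated correlation) rose as lists. Lcn2 was at 0.71 ± 0.19 among the glucocorticoid genes. Pdk1 was at 0.26 ± 0.07 and Adm at 0.22 ± 0.10 among the HIF targets. The count stayed at 0 blocked by run and in the first run, and was 2 without the array of another tissue, 17 with weights, 5 without low-correlation arrays, and 3 without H100 replicate 6.

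Oxygen at 100% without hypoxia (9 N100 against 9 N21 brains) gave 0 genes, with 527 at unadjusted p < 0.05, and Magea6 at -0.46 ± 0.11, Slc22a29 at 0.33 ± 0.08 and Adamts16 at 0.27 ± 0.08 (adjusted p = 1 each). Genes of oxidative phosphorylation (0 of 42, adjusted p = 3e-09, p = 0.84 with estimated correlation) and antioxidant enzymes (0 of 16, adjusted p = 0.0029, p = 0.84 with estimated correlation) fell as lists. Ndufa1 was at -0.38 ± 0.19 and Cox5a at -0.37 ± 0.21 in oxidative phosphorylation. Gpx7 was at -0.29 ± 0.16 and Prdx4 at -0.26 ± 0.15 among the antioxidant enzymes. In 11 H100 against 9 H21 brains (646 at unadjusted p < 0.05) Btbd19 was at -0.36 ± 0.10, Spatc1l at -0.45 ± 0.13 and Rarres1 at -0.37 ± 0.11 (adjusted p = 1 each). Choroid plexus genes rose as a list (0 of 9, adjusted p = 0.016, p = 0.97 with estimated correlation, range 0.00023 to 0.058). Ttr was at 0.26 ± 0.16 and Clic6 at 0.19 ± 0.13. Genes of macrophages and microglia (0 of 14, adjusted p = 0.015, p = 0.97 with estimated correlation) and of oxidative phosphorylation (0 of 42, adjusted p = 0.02, p = 0.97 with estimated correlation) fell, ranges 0.0093 to 0.28 and 0.0057 to 0.98. P2ry12 was at -0.23 ± 0.14 and Marco at -0.22 ± 0.09 among the macrophage and microglia genes. Cox5a was at -0.32 ± 0.20 and Ndufb9 at -0.29 ± 0.21 in oxidative phosphorylation. The slope over oxygen in the 41 hypoxia brains gave 0 genes (811 at unadjusted p < 0.05), with Btnl5-ps at -0.35 ± 0.09, Spatc1l at -0.43 ± 0.12 and Milr1 at -0.39 ± 0.11 (adjusted p = 0.94 each). Genes of macrophages and microglia (adjusted p = 0.021, p = 0.69 with estimated correlation) and of oxidative phosphorylation (adjusted p = 0.023, p = 0.79 with estimated correlation) fell along it, ranges 0.0063 to 0.18 and 0.0063 to 0.96. Tyrobp was at -0.19 ± 0.13 and Fcer1g at -0.18 ± 0.12 among the macrophage and microglia genes. Cox5a was at -0.33 ± 0.19 and Ndufb9 at -0.28 ± 0.19 in oxidative phosphorylation. The interaction gave 0 genes (433 at unadjusted p < 0.05), with Btnl5-ps at -0.69 ± 0.15 (adjusted p = 0.42), Gabre at 0.52 ± 0.14 and Spatc1l at -0.64 ± 0.18 (adjusted p = 1 each), and choroid plexus genes rose in it (0 of 9, adjusted p = 0.026, p = 1 with estimated correlation). Aqp1 was at 0.34 ± 0.24 and Clic6 at 0.30 ± 0.19. Each of the 4 counts was 0 blocked by run and in the first run, and the N100 count 1 with weights.

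In eye, the comparison of all 38 hypoxia with all 18 normoxia arrays, also chosen after the data were examined, called 17 genes, 13 higher and 4 lower. Mt2 rose by 0.73 ± 0.13 (adjusted p = 0.0063, above the normoxia mean in 33 of 38 arrays) and Mt1 by 0.54 ± 0.11 (adjusted p = 0.013, 35 of 38). Pfkp, a phosphofructokinase of glycolysis, rose by 0.52 ± 0.07 (adjusted p = 2.2e-05, 37 of 38). Txnip (0.30 ± 0.06, 34 of 38) and Arrdc3 (0.31 ± 0.06, 36 of 38), arrestin-like regulators of glucose uptake and signalling, and Pik3ip1 (0.33 ± 0.07, 35 of 38), an inhibitor of phosphoinositide 3-kinase, rose with adjusted p of 0.015, 0.015 and 0.016. Ms4a4a (0.73 ± 0.15), the linker histone H1f2 (0.54 ± 0.11), Selenbp1 (0.44 ± 0.08), Pot1a (0.29 ± 0.05), Spidr (0.25 ± 0.06) and Rspo2 (0.25 ± 0.05) rose with adjusted p between 0.0063 and 0.042. Nckap5 (-0.32 ± 0.06, 34 of 38 below the normoxia mean), the muscle gene Ky (-0.31 ± 0.06, 35 of 38), Lsmem1 (-0.29 ± 0.06, 33 of 38) and the mitochondrial malic enzyme Me2 (-0.17 ± 0.04, 35 of 38) fell.

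Of 22 glucocorticoid-responsive genes 2 rose in eye after hypoxia, Mt2 and Mt1, and 20 did not pass, with 8 higher adjusted within the list (list adjusted p = 1e-12, p = 0.01 with estimated correlation). Skeletal muscle genes fell as a list with 0 of 14 called and 9 lower adjusted within the list (mean -0.31, adjusted p = 4.5e-15, p = 0.12 with estimated correlation). Myh4 was at -0.55 ± 0.18 and Pvalb at -0.40 ± 0.18. Of 14 glycolysis genes Pfkp rose, and 2 adjusted within the list (list adjusted p = 0.0011, p = 0.45 with estimated correlation). Mitosis genes rose (0 of 23, adjusted p = 8e-06, p = 0.57 with estimated correlation). Mki67 was at 0.20 ± 0.14 and Tpx2 at 0.20 ± 0.13. Oxidative phosphorylation genes (0 of 42, adjusted p = 1.3e-05, p = 0.57 with estimated correlation) and rod photoreceptors (0 of 11, adjusted p = 0.0017, p = 0.57 with estimated correlation) fell, and 0 members of these 3 lists passed adjusted within the list. Cycs was at -0.19 ± 0.09 and Cox5a at -0.19 ± 0.10 in oxidative phosphorylation. Gnat1 was at -0.42 ± 0.23 and Pde6a at -0.31 ± 0.18 among the rod genes. Vegfa (0.18 ± 0.06), Hmox1 (-0.12 ± 0.09), Fos (0.15 ± 0.06) and Per1 (0.02 ± 0.06) did not pass, Per1 being at -0.01 in the first run. The count of 17 was 53 with weights, 32 blocked by run, 0 in the first run, 8 with the array labelled Eye H40 replicate 9 included, and 26 without N21 replicate 2.

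The single eye comparisons called 0 genes. In 9 H21 against 9 N21 eyes (325 genes at unadjusted p < 0.05) Pfkp was at 0.64 ± 0.13 (adjusted p = 0.24), Lsmem1 at -0.42 ± 0.10 and Fkbp5 at 0.34 ± 0.10 (adjusted p = 1 each). Glucocorticoid-responsive genes rose as a list (0 of 22, 4 adjusted within the list, adjusted p = 2.2e-09, p = 0.084 with estimated correlation). Lcn2 was at 1.26 ± 0.56 and Mt2 at 0.71 ± 0.22. Skeletal muscle genes (0 of 14, adjusted p = 2.6e-07, p = 0.79 with estimated correlation), genes of oxidative phosphorylation (0 of 42, adjusted p = 5.5e-07, p = 0.96 with estimated correlation, range 1.7e-08 to 0.18) and of cholesterol synthesis (0 of 15, adjusted p = 0.0076, p = 0.63 with estimated correlation, range 6.4e-05 to 0.14) fell. Myh8 was at -0.45 ± 0.31 and Casq1 at -0.41 ± 0.28 among the skeletal muscle genes. Ndufa1 was at -0.27 ± 0.19 and Cyc1 at -0.19 ± 0.11 in oxidative phosphorylation. Msmo1 was at -0.26 ± 0.14 and Fdft1 at -0.16 ± 0.10 among the cholesterol synthesis genes. The count was 0 blocked by run and in the first run, and 1 with weights, without N21 replicate 2 or without the array of another tissue.

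In 10 H40 against 9 N21 eyes (839 genes at unadjusted p < 0.05) Angpt1 was at -0.48 ± 0.11, Asb5 at -0.73 ± 0.19 and Mypn at -0.48 ± 0.13 (adjusted p = 0.96 each). Skeletal muscle genes fell as a list (mean -0.65, 0 of 14 called and 12 lower adjusted within the list, adjusted p = 7.8e-16, p = 0.13 with estimated correlation), and glucocorticoid-responsive genes rose (0 of 22, adjusted p = 7.1e-07, p = 0.13 with estimated correlation, range 1.5e-06 to 0.3). Myh4 was at -0.87 ± 0.32 and Myh1 at -0.86 ± 0.36 among the skeletal muscle genes. Lcn2 was at 1.09 ± 0.54 and Mt2 at 0.55 ± 0.22 among the glucocorticoid genes. Lens crystallins fell (0 of 17, adjusted p = 1.2e-08, p = 0.31 with estimated correlation) and type 2 alveolar cell genes rose (0 of 12, adjusted p = 5e-07, p = 0.13 with estimated correlation). Crygd was at -0.98 ± 0.57 and Crygc at -0.90 ± 0.51 among the crystallins. Sftpc was at 1.41 ± 0.53 and Sftpa1 at 0.69 ± 0.34 among the alveolar genes. Without the array labelled Eye H40 replicate 9 their adjusted p became 0.38 and 0.011 (ranges 1.5e-08 to 0.38 and 1.4e-06 to 0.22). The count was 0 blocked by run, in the first run and without that array.

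In 9 H60 against 9 N21 eyes (806 genes at unadjusted p < 0.05) Pfkp was at 0.56 ± 0.13, Alg13 at 0.30 ± 0.08 and Serinc5 at 0.47 ± 0.13 (adjusted p = 1 each). Genes of oxidative phosphorylation (mean -0.24, 0 of 42, adjusted p = 4.8e-24, p = 0.21 with estimated correlation) and skeletal muscle (0 of 14, adjusted p = 0.00036, p = 0.93 with estimated correlation) fell as lists, and extracellular matrix genes rose (0 of 22, adjusted p = 0.0011, p = 0.93 with estimated correlation, range 0.00058 to 0.48). Cox5a was at -0.46 ± 0.16 and Ndufb8 at -0.46 ± 0.19 in oxidative phosphorylation. Pvalb was at -0.50 ± 0.34 and Mylpf at -0.45 ± 0.26 among the skeletal muscle genes. Mmp9 was at 0.72 ± 0.42 and Col1a2 at 0.37 ± 0.27 among the extracellular matrix genes. In 11 H100 against 9 N21 eyes (852 genes at unadjusted p < 0.05) Pfkp was at 0.54 ± 0.13, Tnfrsf11b at -0.35 ± 0.09 and Akap4 at 0.32 ± 0.08 (adjusted p = 0.83 each). Glucocorticoid-responsive genes (0 of 22, adjusted p = 2.7e-06, p = 0.42 with estimated correlation) and glycolysis genes (0 of 14, 1 adjusted within the list, adjusted p = 0.00063, p = 0.99 with estimated correlation, range 0.00012 to 0.28) rose, and genes of oxidative phosphorylation fell (0 of 42, adjusted p = 0.00063, p = 0.99 with estimated correlation, range 0.00072 to 0.051). Lcn2 was at 0.87 ± 0.53 and Bcl6 at 0.43 ± 0.26 among the glucocorticoid genes. Hk2 was at 0.35 ± 0.17 among the glycolysis genes. Cycs was at -0.32 ± 0.15 and Ndufv2 at -0.27 ± 0.13 in oxidative phosphorylation. Both counts were 0 blocked by run and in the first run, and 1 without N21 replicate 2.

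In 11 H100 against 9 N100 eyes (1393 genes at unadjusted p < 0.05) Tmem35b was at 0.38 ± 0.08 (adjusted p = 0.33), Pik3ip1 at 0.47 ± 0.11 and Mvb12b at -0.39 ± 0.09 (adjusted p = 0.35 each). Glucocorticoid-responsive genes (0 of 22, 2 adjusted within the list, adjusted p = 1e-06, p = 0.33 with estimated correlation) and mitosis genes (0 of 23, adjusted p = 0.00036, p = 0.98 with estimated correlation) rose as lists. Mt2 was at 0.88 ± 0.21 and Lcn2 at 0.85 ± 0.53 among the glucocorticoid genes. Cdc20 was at 0.42 ± 0.16 and Kif11 at 0.34 ± 0.23 among the mitosis genes. The count of 0 was 406 with weights, 1 blocked by run, 0 in the first run and 2 with only these groups in the fit. It was 3 without H100 replicate 6 and 1 without H100 replicate 2 or N100 replicate 2.

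Oxygen at 100% without hypoxia (9 N100 against 9 N21 eyes) gave 0 genes, with 563 at unadjusted p < 0.05, and Dusp7 at 0.24 ± 0.07, Dot1l at 0.22 ± 0.06 and Pacs1 at 0.23 ± 0.07 (adjusted p = 0.99 each). Genes of oxidative phosphorylation (0 of 42, adjusted p = 1.3e-06, p = 1 with estimated correlation, range 3.4e-06 to 0.079), mitosis (0 of 23, adjusted p = 0.00024, p = 1 with estimated correlation) and DNA replication (0 of 28, adjusted p = 0.00061, p = 1 with estimated correlation) fell as lists. Ndufa6 was at -0.45 ± 0.19 and Ndufb8 at -0.30 ± 0.19 in oxidative phosphorylation. Ncapg was at -0.36 ± 0.25 and Ube2c at -0.34 ± 0.17 among the mitosis genes. Prim1 was at -0.31 ± 0.16 and Pcna at -0.29 ± 0.19 among the DNA replication genes. In 11 H100 against 9 H21 eyes limma called 0 genes (676 at unadjusted p < 0.05) and camera 0 of 47 lists, and Ost4 was at 0.36 ± 0.10, Acot6 at 0.28 ± 0.08 and Thap12 at -0.21 ± 0.06 (adjusted p = 1 each). The slope over oxygen in the 39 hypoxia eyes gave 0 genes (850 at unadjusted p < 0.05), with Pcyt1a at 0.34 ± 0.09, Ost4 at 0.32 ± 0.09 and Samd5 at -0.25 ± 0.08 (adjusted p = 0.97 each). Skeletal muscle genes (adjusted p = 0.011, p = 0.99 with estimated correlation, range 4.4e-05 to 0.063) and glycolysis genes (adjusted p = 0.018, p = 0.99 with estimated correlation, range 0.003 to 0.84) rose along it, with 0.063 each without the array labelled Eye H40 replicate 9. Myh8 was at 0.55 ± 0.32 and Myh1 at 0.50 ± 0.36 among the skeletal muscle genes. Pfkm was at 0.47 ± 0.20 and Hk2 at 0.39 ± 0.18 among the glycolysis genes. The interaction gave 0 genes (608 at unadjusted p < 0.05), with Htr6 at -0.43 ± 0.14, Bsph1 at -0.41 ± 0.13 and Naip6 at 0.67 ± 0.21 (adjusted p = 1 each). Genes of oxidative phosphorylation (adjusted p = 0.00023, p = 1 with estimated correlation) and mitosis (adjusted p = 0.0043, p = 1 with estimated correlation) rose in it, ranges 0.00034 to 0.12 and 2.4e-16 to 0.069. Sdhd was at 0.42 ± 0.23 and Ndufa1 at 0.38 ± 0.26 in oxidative phosphorylation. Cdc20 was at 0.45 ± 0.23 and Top2a at 0.45 ± 0.35 among the mitosis genes. Each of the 4 counts was 0 blocked by run and in the first run.

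Whether tissues differed in the H21 minus N21 change was tested in 1 fit. Lists called numbered 5 between lung and brain, 8 between lung and eye and 2 between brain and eye, and 8, 14 and 6 for all hypoxia minus all normoxia. Gdpd2 was called, with a change 0.97 ± 0.19 higher in lung than in brain (adjusted p = 0.019, 251 genes at unadjusted p < 0.05). DNA replication genes were lower in lung than in brain as a list (0 of 28, adjusted p = 1.5e-08, p = 0.82 with estimated correlation) and neutrophil genes higher (0 of 12, 1 adjusted within the list, adjusted p = 6.2e-05, p = 0.73 with estimated correlation). Gins2 was at -0.32 ± 0.14 and Mcm7 at -0.31 ± 0.17 among the DNA replication genes. Mmp8 was at 1.04 ± 0.26 and Cxcr2 at 0.77 ± 0.29 among the neutrophil genes. Skeletal muscle, lymphocyte and glucocorticoid-responsive lists were also higher in lung (adjusted p = 0.0097, 0.017 and 0.017, p = 0.98 each with estimated correlation). Between lung and eye limma called 0 genes (350 at unadjusted p < 0.05), with Gdpd2 at 0.84 ± 0.19 (adjusted p = 0.16, as for Fhl5) and Prkcq at 0.55 ± 0.13 (adjusted p = 0.39). Skeletal muscle genes were higher in lung than in eye (0 of 14, adjusted p = 6.7e-09, p = 0.57 with estimated correlation) and DNA replication genes lower (0 of 28, adjusted p = 6.9e-07, p = 0.59 with estimated correlation). Myh8 was at 1.31 ± 0.76 and Acta1 at 1.07 ± 0.66 among the skeletal muscle genes. Mcm6 was at -0.35 ± 0.21 and Rfc5 at -0.32 ± 0.18 among the DNA replication genes. Another 6 lists were higher in lung: neutrophils (1 adjusted within the list), smooth muscle and pericytes, heat shock proteins, macrophages, HIF targets and lymphocytes. Adjusted p was 4e-04 to 0.042 (0.57 to 0.95 with estimated correlation). Between brain and eye limma called 0 genes (142 at unadjusted p < 0.05), with Pmp2 at 1.48 ± 0.38, Slc16a3 at 0.71 ± 0.19 and Pfkp at -0.66 ± 0.20 (adjusted p = 1 each), and skeletal muscle genes were higher in brain (0 of 14, adjusted p = 0.0098, p = 0.99 with estimated correlation), as were those of oxidative phosphorylation (adjusted p = 0.014, p = 0.99 with estimated correlation). Mylpf was at 0.49 ± 0.47 and Myh8 at 0.45 ± 0.76. With group and number as a block the counts were 2, 0 and 0, with weights 24, 12 and 0, and without the arrays of another tissue 5, 2 and 0.

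The same test on all hypoxia minus all normoxia, chosen after the data were examined, called 90 genes between lung and brain, 61 with a higher and 29 with a lower change in lung. Fhl5 (1.35 ± 0.19, adjusted p = 1e-07), Dpep1 (1.07 ± 0.15, adjusted p = 7.2e-08), Mmp8 (0.95 ± 0.15), Fmo2 (0.89 ± 0.16) and Adamtsl2 (0.80 ± 0.11) had the largest differences upward in lung. Hmox1 (-0.78 ± 0.14, adjusted p = 0.00016), Slitrk6 (-0.72 ± 0.17), Ctla2a (-0.71 ± 0.18), Cxcl10 (-0.67 ± 0.17) and A2m (-0.64 ± 0.12) had the largest downward. DNA replication genes were lower in lung (0 of 28, adjusted p = 1.9e-08, p = 0.63 with estimated correlation), neutrophil genes higher (1 of 12, Mmp8, 5 adjusted within the list, adjusted p = 2e-06, p = 0.21 with estimated correlation) and glucocorticoid-responsive genes higher (1 of 22, Sgk1 0.42 ± 0.09, 8 higher and 2 lower adjusted within the list, adjusted p = 0.0015, p = 0.63 with estimated correlation). Mcm6 was at -0.28 ± 0.12 and Mcm7 at -0.27 ± 0.10. Between lung and eye 79 genes were called, 56 with a higher and 23 with a lower change in lung. Fhl5 (1.26 ± 0.19), Dpep1 (0.95 ± 0.15), Mmp8 (0.85 ± 0.15), Ntrk2 (0.78 ± 0.09, adjusted p = 6.9e-11) and Wfdc1 (0.77 ± 0.12) led upward, and Slitrk6 (-0.99 ± 0.17, adjusted p = 1e-04), Rspo2 (-0.70 ± 0.10), Adh1 (-0.58 ± 0.15), Adam12 (-0.58 ± 0.10) and Unc5c (-0.56 ± 0.12) downward. DNA replication genes were lower in lung than in eye (0 of 28, adjusted p = 1.6e-12, p = 0.18 with estimated correlation). Mcm6 was at -0.33 ± 0.12 and Uhrf1 at -0.30 ± 0.15. Genes of smooth muscle and pericytes (0 of 10, 1 adjusted within the list, adjusted p = 8.5e-05, p = 0.13 with estimated correlation) and skeletal muscle (0 of 14, adjusted p = 0.00013, p = 0.5 with estimated correlation) were higher. Des was at 0.29 ± 0.14 and Myh11 at 0.27 ± 0.14 among the smooth muscle and pericyte genes. Myh4 was at 0.60 ± 0.22 and Pvalb at 0.47 ± 0.22 among the skeletal muscle genes. Between brain and eye Hmox1 was higher by 0.83 ± 0.14 in brain (adjusted p = 0.00064) and Pfkp was at -0.52 ± 0.10 (adjusted p = 0.0083). Skeletal muscle (0 of 14, adjusted p = 4e-06, p = 0.65 with estimated correlation) and rod photoreceptor genes (0 of 11, adjusted p = 0.00014, p = 0.65 with estimated correlation) were higher in brain. Myh4 was at 0.63 ± 0.23 and Myh1 at 0.41 ± 0.33 among the skeletal muscle genes. Gnat1 was at 0.35 ± 0.20 and Pde6a at 0.31 ± 0.16 among the rod genes. With group and number as a block, which kept the 90, 79 and 2 genes, the counts were 142, 135 and 4, with weights 294, 300 and 11, and with the 3 arrays of another tissue included 30, 20 and 1.

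**Figure D3:**
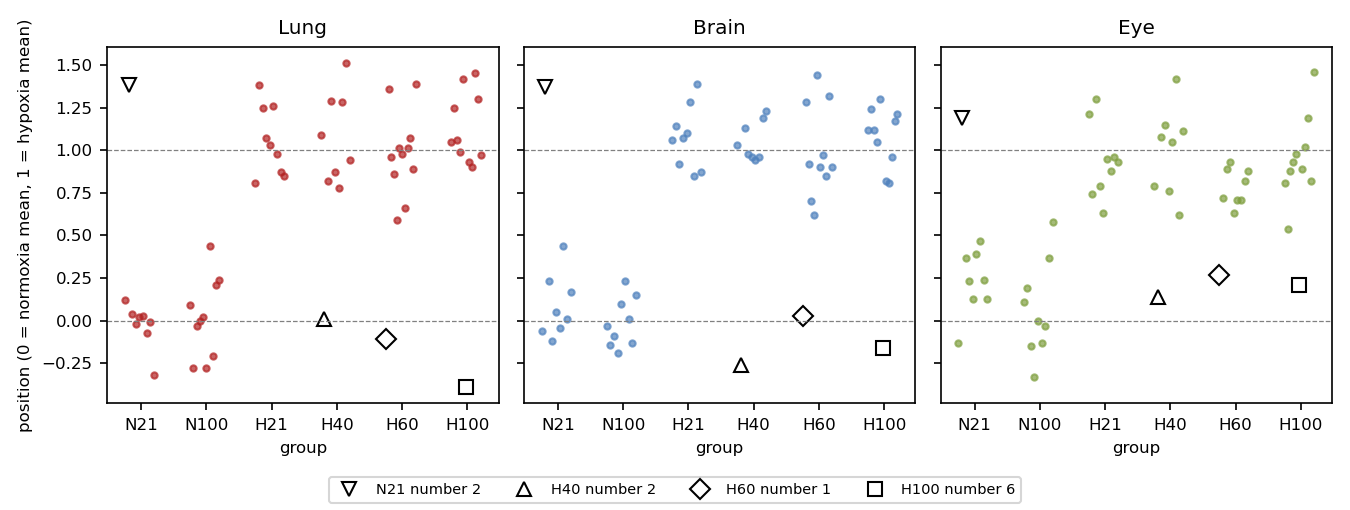
Position of each array between the normoxia mean (0) and the hypoxia mean (1) of its tissue (vertical axis, no unit) over 50 genes ranked without that array, by exposure group and tissue (horizontal axis); each point is 1 array, and the arrays of N21 number 2, H40 number 2, H60 number 1 and H100 number 6 are marked. Of 174 arrays 13 lie across the middle at 0.5, and 12 of these are the 3 tissues of the marked animals.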

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

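The tests on the 3 arrays, the 4 animals, the shared numbers and the clock genes were chosen after the results were seen, and so were the comparison of all hypoxia with all normoxia arrays and its tissue differences. Of 252 groups of 4 to 10 arrays, 33 held an array far from the others by the gap to its nearest neighbour as a share of the group's range (the ratio given here), and chance gives about 5% of groups such an array.

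In lung, N21 replicate 2 lay apart from the other N21 arrays, with ratios of 0.66 for Glul, 0.774 for Fhl5 (7.65 against 5.46 ± 0.20 SD), 0.63 for Dpep1, 0.527 for Adamtsl2 and 0.521 for Adm, all upward, and 0.786 for Slc27a6 and 0.534 for Wnt2, both downward. H40 replicate 2 was lowest in Fhl5 (0.532) and highest in Adam12 (0.575). H21 replicate 1 was lowest in Slitrk6 (0.525), Slc27a6 (0.513), Iigp1 (0.594), Adam12 (0.715) and Tafa1 (0.655), and H21 replicate 5 highest in Stc1 (0.49). N100 replicate 10 was lowest in Ntrk2 (0.47) and Ptprd (0.551), and N100 replicate 7 highest in Adm (0.524).

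In brain, N21 replicate 2 was highest in Mt2 (0.601, 11.69 against 10.40 ± 0.25 SD), Hmox1 (0.542) and Lcn2 (0.704). H40 replicate 2 was lowest in Serpina3n (0.748, 6.77 against 8.06 ± 0.11 SD), Adgrl4 (0.562) and C5ar1 (0.582), and N21 replicate 3 lowest in Adgrl4 (0.622). In eye, H40 replicate 2 was lowest in Pfkp (0.546), H21 replicate 5 lowest in Mt2 (0.541) and H21 replicate 9 highest in Me2 (0.532). N21 replicate 7 was highest in Mt1 (0.573) and N100 replicate 9 highest in H1f2 (0.561).

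The 3 arrays of another tissue were far from the others in the type 2 alveolar cell (0.899), neuron (0.824) and lens crystallin (0.915) lists. Over genes that differ by more than 3 on the log2 scale between the tissues, they lay 93.5% of the way from lung to brain, 92.6% from brain to eye and 87.1% from eye to lung. The lowest arrays of those tissues lay at 96.2%, 94.5% and 91.8%. These values argue against a mixture with the labelled tissue as the larger part. A wrong tissue label of a whole sample and a small share of the labelled tissue in a sample of another both stay open. All 3 arrays carried a male signal (3 of 3, against 4 of 27 other H40 arrays), so whether they are tissues of 1 animal with rotated labels stays open; no biological explanation was tested.

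The animals N21 number 2, H40 number 2, H60 number 1 and H100 number 6 lay on the other exposure's side in lung, brain and eye, with mean positions of 1.31, -0.04, 0.06 and -0.11 between the normoxia mean at 0 and the hypoxia mean at 1. Noise of single arrays is argued against, since 4 of 37 sets of 3 first-run arrays with the same group and number had all of them across the middle and 10000 shuffles gave at most 2. The first submission run as the cause is argued against by 59 of 59 other first-run arrays of these groups on their own side. A wrong group label of the animal may explain all 4; a weak response of an animal exposed as labelled is excluded for N21 number 2, which breathed no low-oxygen gas per its label, and stays open for the other 3. That a number marks the same animal in different tissues was tested by sex, and 110 of 112 pairs in the first run, which holds these 4, had the same sex signal against 66.3 expected by chance. With an array of a later run 37 of 55 did against 28.9 expected and 18 differed, which argues against it there; no fit leaves these 4 animals out together, because they were picked by the response under test.

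Of 16 clock genes 6 passed in lung after hypoxia: Cry1 rose by 0.37 ± 0.05 (adjusted p = 5.3e-06), Cry2 by 0.24 ± 0.04, Arntl by 0.23 ± 0.05 and Per2 by 0.24 ± 0.06, and Nr1d1 changed by -0.44 ± 0.08 and Nr1d2 by -0.38 ± 0.07, while the other 10, Per1 among them, and the list (adjusted p = 0.74) did not pass. Uneven submission runs are argued against as the whole cause, since 6 of 6 were called with the run as a block. A glucocorticoid response of the lung may contribute, but the correlation of the clock score with the glucocorticoid list within groups was r = 0.225 over 60 arrays (permutation p = 0.099, Benjamini-Hochberg adjusted 0.149 over 3 tissues; rho = 0.178, p = 0.19). It was 0.189 without the 2 farthest arrays, 0.176 within the first run and 0.292 in the later ones, so it stays open. Another time of day at sampling stays open as well: 0 of 12 values of these genes were called by limma in brain and eye, and the tissue difference was called for Arntl (0.33 ± 0.07) and Nr1d2 (-0.31 ± 0.08) between lung and brain and Nr1d2 (-0.38 ± 0.08) between lung and eye.

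The other results singled out differed between tissues. In the H21 minus N21 change these were Gdpd2 (0.97), DNA replication (-0.17) and neutrophil genes (0.33) between lung and brain. Others were DNA replication (-0.16) and skeletal muscle genes (0.74) between lung and eye, and skeletal muscle genes (0.35) between brain and eye. Lists are mean differences. For all hypoxia minus all normoxia, lung minus brain gave Fhl5 1.35, Dpep1 1.07, Mmp8 0.95, Fmo2 0.89, Adamtsl2 0.80, Hmox1 -0.78, Slitrk6 -0.72, Ctla2a -0.71, Cxcl10 -0.67 and A2m -0.64, with DNA replication at -0.13, neutrophils at 0.30 and glucocorticoid-responsive genes at 0.10. Lung minus eye gave Fhl5 1.26, Dpep1 0.95, Mmp8 0.85, Ntrk2 0.78, Wfdc1 0.77, Slitrk6 -0.99, Rspo2 -0.70, Adh1 -0.58, Adam12 -0.58 and Unc5c -0.56, with DNA replication at -0.17, smooth muscle and pericytes at 0.19 and skeletal muscle at 0.34. Brain minus eye gave Hmox1 0.83 and Pfkp -0.52, with skeletal muscle at 0.33 and rod photoreceptors at 0.16.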

How the results depend on the processing

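All fits of all hypoxia against all normoxia and fits within the first run were chosen after the data were examined. So were fits with or without the arrays of another tissue (1 per tissue), without low-correlation arrays or each array in turn. Of refitted gene counts, mostly of 0 genes, 1054 stayed within 1.5 times and 117 moved. Of list values 551 kept direction and side of the threshold, 180 lost the threshold (100 with estimated correlation, which kept 12) and 1 reversed. Of named-gene values 3702 kept both, 69 passed newly, 132 lost the threshold and 17 reversed. Quantile normalization again moved 0 counts and kept 30, weights 17 and 19, and leaving out the dimmest 40% of genes 2 and 34. The cause was not tested for the changes below, except that fits within the first run hold fewer arrays.

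For lung H21 minus N21 (3 genes), array quality weights gave 133, the dim genes left out 5, the first run 0, only these groups 1, the replicate block 5, a sex covariate 0, the run as a block 5, the arrays of another tissue left out 10 and low-correlation arrays left out 27. For lung H40 minus N21 (0) weights gave 4, and the dim genes left out, the run as a block, and either kind of array left out gave 1 each. For lung H60 minus N21 (0) weights gave 4 and low-correlation arrays left out 2, for H100 minus N21 (0) weights 8 and either kind of array left out 4, for N100 minus N21 (0) the run as a block 1, and for the slope over oxygen (0) the first run 1. For lung H100 minus N100 (5) weights gave 183, every probe set 1, the first run 0 and only these groups 10. Arrays of another tissue left out gave 21, low-correlation ones 28.

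For brain H100 minus N100 (0) weights gave 17, arrays of another tissue left out 2 and low-correlation ones 5. For N100 minus N21 (0) weights gave 1. For eye H100 minus N100 (0) weights gave 406, only these groups 2, and the run as a block and low-correlation arrays left out 1 each. For eye H21 minus N21 (0) weights and either kind of array left out gave 1. For all hypoxia minus all normoxia, lung (331) had 834 with weights, 23 in the first run, 504 with the run as a block and 95 with the arrays of another tissue. Brain (17) had 41 with weights, 4 in the first run and 30 without low-correlation arrays, and eye (17) 53, 0 in the first run, 32 with the run as a block and 8 with the arrays of another tissue.

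Between lung and brain the H21 minus N21 difference (1) had 24 with weights, 2 with the replicate block and 5 without the arrays of another tissue, and between lung and eye (0) 12 with weights and 2 without those arrays. For all hypoxia minus all normoxia the differences between lung and brain (90) had 294, 142 with the replicate block and 30 with the arrays of another tissue; lung and eye (79) had 300, 135 and 20, and brain and eye (2) had 11, 4 and 1. Across tissues the replicate block is group and number, not always 1 animal: 18 of 55 pairs with a later-run array differed in sex signal. Across groups 38 of 64 same-number pairs in lung, 34 of 62 in brain and 26 of 62 in eye correlated above 0.1. Pairing within a tissue stays open, and the block moved no other count there.

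Leaving out 1 array at a time gave 0 to 16 genes for lung H21 minus N21, 0 to 4 for H40, 0 to 2 for H60 and 0 to 6 for H100 against N21, 1 to 25 for H100 minus N100 and 262 to 418 for all hypoxia minus all normoxia. In brain it gave 0 to 1 for H21, H40 and H100 against N21, 0 to 3 for H100 minus N100 and 11 to 32 for all hypoxia. In eye it gave 0 to 1 for H21, H60 and H100 against N21, 0 to 3 for H100 minus N100 and 12 to 26 for all hypoxia. Each remaining comparison stayed at 0.

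Reversed values were Crygd in brain H40 minus N21 (-0.04 with weights, -0.03 in the first run, -0.08 without low-correlation arrays) and its lens crystallin list (-0.00 without low-correlation arrays), Rag1 in lung H21 minus N21 (-0.31 with weights) and in the lung interaction (0.13 with weights), and Sftpc in lung H40 minus N21 (0.02 in the first run and without either kind of array). For all hypoxia minus all normoxia they were Cry2 in brain (-0.01 with weights, -0.02 with the arrays of another tissue) and eye (0.01 without low-correlation arrays), Nr1d2 in eye (-0.01 in the first run and without low-correlation arrays, -0.02 with the arrays of another tissue), Per1 in eye (-0.01 in the first run, -0.00 with the replicate block) and Fos in lung (-0.01 with the arrays of another tissue).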

Other observations

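The bound for the split tests, the splits inside the runs, and the comparison of all hypoxia with all normoxia were chosen after the data were examined. Each comparison was refitted on 100 splits of the same arrays into groups of the same sizes, the real one included. These splits ignore the submission run, so the counts above 0 were also refitted on 100 splits inside the first and the later runs.

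Chance can be excluded for lung H21 minus N21 (3 genes, highest other split 2, 1 of 100 as large, highest other inside the runs 0), lung H100 minus N100 (5, highest other 2, 1 of 100, inside the runs 0), and all hypoxia minus all normoxia in lung (331, highest other 3174, 3 of 100, inside the runs 1), brain (17, highest other 7, 1 of 100, inside the runs 0) and eye (17, highest other 511, 3 of 100, inside the runs 0). The splits ignore animals shared by tissues. With that limit chance can be excluded too for 2 tissue differences of that comparison. These are lung and brain (90, highest other 590, 3 of 100, inside the runs 2) and lung and eye (79, highest other 66, 1 of 100, inside the runs 125, 2 of 100). The 3 lung genes of H21 minus N21 depend on single arrays: the count was 0 with a sex covariate, within the first run, and without any 1 of N21 replicates 1, 5, 7 and 9. The 5 of H100 minus N100 do as well: 19 of the 21 arrays moved the count over 1.5 times when left out, mostly to 1 or 2, no more than the highest other split, and it was 0 within the first run. In the splits that ignore the run, 5 or more of 100 were as large in 2 tissue differences, so chance stays open there. These were the difference between brain and eye (2, highest other 61, 7 of 100, inside the runs 196, 4 of 100) and the H21 minus N21 difference between lung and brain (1, highest other 4, 5 of 100, inside the runs 1, 2 of 100).

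Where limma called 0 genes, 100 of 100 splits gave as many by necessity, so they decide nothing. The highest other splits in lung gave 72 for H40, 0 for H60, 2 for H100 and 1 for N100 against N21, 1 for H100 minus H21, 116 for the slope over oxygen and 27 for the interaction. In brain they gave 8, 2940, 1, 0 and 1 for H21, H40, H60, H100 and N100 against N21, 1 for H100 minus H21, 1 for H100 minus N100, 1 for the slope and 2 for the interaction. In eye they gave 201, 470, 0, 512 and 0 in the same order against N21, 38 for H100 minus H21, 2 for H100 minus N100, 0 for the slope and 1 for the interaction. The H21 minus N21 differences gave 314 between lung and eye and 952 between brain and eye. Splits far above the real count, such as 3174 against 331 in lung and 511 against 17 in eye, point to a sample structure other than the exposure.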
